A study of Mus musculus with 12 samples.

How the data were processed

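DNA copy number was measured by array comparative genomic hybridisation on 12 Agilent mouse arrays of 60-mer oligonucleotide probes. Each array compared DNA from cultured malignant peripheral nerve sheath tumour (MPNST) cells with DNA from wild-type, non-neoplastic Schwann cells. The tumours arose in transgenic mice that overexpress the neuregulin-1 isoform GGFβ3 in Schwann cells. Tumour DNA carried Cy5 and reference DNA carried Cy3 on every array, with no dye swap, so a dye effect cannot be told apart from a tumour effect. The labels name 11 tumours, 7 on a mixed C57BL/6J x SJL/J background and 4 on C57BL/6J. Tumour A382 was hybridised at passages 8 and 9, and its 2 arrays were averaged so that it counts once. The tumours are treated as independent as far as their labels name them apart, and a p-value measures only the spread between these samples.

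The deposited ratios are log10 of tumour over reference signal, per the file headers. The scanner software had subtracted background, corrected for spatial trend and multiplicative trend, and normalised the dyes linearly within each array. The files also give the brightness of each channel as intensity, both as scanned and after that processing, per the file headers. The submitters' processing notes name Agilent Feature Extraction 9.5 and genome build mm9, and all coordinates below are in mm9 as the files give them. No annotation of that build was used here, so exon and intron positions are not given. The series value table held the same log10 ratios, with a largest absolute difference of 0.

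Ratios were converted to log2. Control spots were dropped, which left 43020 spots, and spots that the scanner software marked as non-uniform or as outliers of their replicate population were set to missing. Spots of the same probe were averaged, giving 42404 probes, of which 40726 lay on autosomes and 1569 on X, while 109 had no chromosome position. Each array was centred on the median of its autosomal probes. Gene values are the mean of a gene's probes. Gene names came from the files, and 2495 were updated through RefSeq accessions, which matched for 28951 of 29337 probes that carried one. This gave 19984 autosomal names, of which 4730 were cDNA accessions, and 45.4% of genes had a single probe. Mtor and its older name Frap1 were both on the arrays and counted separately. The median spacing of autosomal probes was 21.5 kb.

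The 4 arrays of slide 1 (A18, 231 Trig, B86 and A202) were read on another scanner than the 8 arrays of slides 2 and 3, and their replicate spots spread more widely, by a median of 16.1% to 23.7% against 8.22% to 12.2%. Median net signal was 612 to 809 in the reference channel and 538 to 1237 in the tumour channel. No spot was saturated, and at least 99.4% of probes were well above background in both channels on each array. The number of arrays limits the precision of every value.

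Genes were tested with limma 3.58.1 in R 4.3.3, as the mean log2 ratio over the 11 tumours against 0. The reference sits on every array, so its own spread is not in this test. A gene passed with a Benjamini-Hochberg adjusted p under 0.05 and a mean of at least 0.2 in absolute log2. It is then said to have risen or fallen against the reference. Genes with enough values for the test numbered 19970. The strain backgrounds were compared with limma in the same way. Chromosome medians were tested with an exact two-sided sign-flip permutation test, and the strain backgrounds by an exact two-sided permutation test over the 330 splits of the tumours, each with Benjamini-Hochberg adjustment over the 19 autosomes. Profiles were segmented by penalised least squares, with a penalty of 40 noise variances per break and at least 5 probes per segment. Values of isolated probes were limited to 3 noise SD around the running median of 5 probes. A segment was called at a mean log2 of at least 0.2 or at most -0.2. Recurrence was tested against 1000 random circular shifts of each tumour's calls along the autosomes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for these steps.

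The tests, the main settings other than those named next, most alternatives, gene lists and the rule for named genes were chosen before the data were examined. The rule took the 5 highest and 5 lowest mean ratios among passing genes with the same sign in at least 9 of 11 tumours, at most 1 per chromosome and direction. It added up to 4 members of each list, 14 genes named whatever their values, up to 3 genes of each tumour's highest and lowest segment, the passing genes of the strain comparison, and up to 5 genes that differed between the passages. The lists were tumour suppressors of MPNST and nerve sheath tumours, receptor tyrosine kinases and ligands, Ras, MAPK and PI3K signalling, cell cycle with mitosis and Myc, DNA damage response and telomere, Schwann cell lineage, loci known to differ in copy number between inbred strains, and lymphocyte antigen receptor loci. Genes that are not reported here were left out of the named genes and, after the data were seen, of the list tests, with 1 further list. The lists were tested with fry from limma. Its directional p asks whether the members of a list move, on balance, one way, its mixed p whether they change in either direction, and neither compares the list with other genes.

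The alternatives were normexp background correction with an offset of 50, loess on those values, the series value table, centring on the mode, probes well above background on all arrays (461 probes removed), single probes, a running median of 5 probes, other size minimums, either A382 array alone, slide as a block, equal weight for the strain backgrounds, C57BL/6J tumours only, each tumour left out, and other thresholds, penalties and segment lengths. Leaving out slide 1, leaving out chromosome 11, segmentation without limiting isolated probes, slide as a block for the lists, comparisons within slides, and leaving out each tumour for the shares and the passage correlation were added later, with the data at hand. So were the masking of marked spots, the limit on missing values (at most 2 tumours and at most 1 C57BL/6J tumour) and the limiting of isolated probes before segmentation.

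The steps were tested on simulated data. Over 19626 simulated genes, the test across tumours recovered 31.3%, 82.1% and 98.5% of genes changed by 0.2, 0.4 and 0.8 in log2, with 5 unchanged genes passing. Unchanged genes were simulated as independent noise around 0. That count therefore does not cover offsets of a probe or of the reference that repeat on every array. The strain test recovered 0%, 22.4% and 80.3% of genes at the same sizes. Simulated segments of 50 probes at 0.6 were all found, those of 10 probes in 69.9% of cases and those of 5 probes in 2.39%. At 0.3 those of 50 probes were found in 87.6% of cases, and those of 10 or 5 probes in 0%. X was left out of centring, shares and recurrence, and Y was not analysed here.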

Results

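Copy number was profiled in MPNST cells, cultured from tumours of the nerve sheath in mice that overexpress the neuregulin-1 isoform GGFβ3 in Schwann cells. The 12 arrays covered 11 tumours, 7 on the mixed C57BL/6J x SJL/J background (A18, 231 Trig, A202, A390, A292, A382 and A394) and 4 on C57BL/6J (B86, B91, B96 and B76), each against wild-type Schwann cell DNA whose strain is given as C57BL/6J. Passage numbers from 5 to 13 stand in the titles of 10 tumours and were used, although the growth notes set an upper limit below several of them. The spread of log ratios between neighbouring probes was 0.181 to 0.245 per array. The 3 highest of these values came from slide 1, where 0.72% to 1.99% of spots were set to missing, against 0.06% to 0.11% on the other slides.

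The first comparison, of tumour cells with non-neoplastic Schwann cells, asks which chromosomes and genes differ in copy number. Chromosome 11, which carries the tumour suppressors Nf1, Trp53, Nf2 and Suz12 and the receptor genes Egfr and Erbb2, was above the reference in all 11 tumours, with a mean of the chromosome medians of 0.69 ± 0.19 log2 (SD, n = 11). The lowest tumour was B91 at 0.41 and the highest was A202 at 1.06. Chromosome 6 was also higher at 0.15 ± 0.21 (SD, n = 11), in 8 of 11 tumours, with B91 at 0.67. Chromosomes 4, 9, 13, 16 and 18 were lower, by small mean amounts of -0.08, -0.10, -0.12, -0.10 and -0.14. In total 7 of 19 autosomes passed the exact sign-flip permutation test, 2 higher and 5 lower. Chromosome 11 had an exact sign-flip p of 0.000977, the smallest this test can give, and an adjusted p of 0.00371. Chromosomes 4, 13, 16 and 18 were below 0 in 11 of 11 tumours with the same adjusted p, chromosome 9 had 0.0155 and chromosome 6 had 0.0451. On chromosomes 4, 13, 16 and 18 only 1, 2, 2 and 1 of the 11 tumours reached -0.2. In the C57BL/6J tumours their means were -0.08 ± 0.02, -0.10 ± 0.03, -0.06 ± 0.01 and -0.15 ± 0.03 (SD, n = 4). A small offset of the reference or dye that repeats on every array would also pass, so the test cannot tell it from losses in the tumours. The call on chromosome 6 ended, at adjusted p of 0.0557 to 0.0901, when A18, B86, A390, B91 (0.10 without it), A292, A382, B76 or A394 was left out. Leaving out 1 tumour brought chromosomes 2 (-0.07 without A202 or A390), 5 (-0.08 without A202), 8 (-0.15 without B76), 10 (-0.08 without A382) and 14 (-0.13 without B76) past the threshold. With centring on the mode chromosome 3 passed at 0.11, and chromosomes 9 (-0.07) and 16 (-0.07) did not pass.

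**Figure D1:**
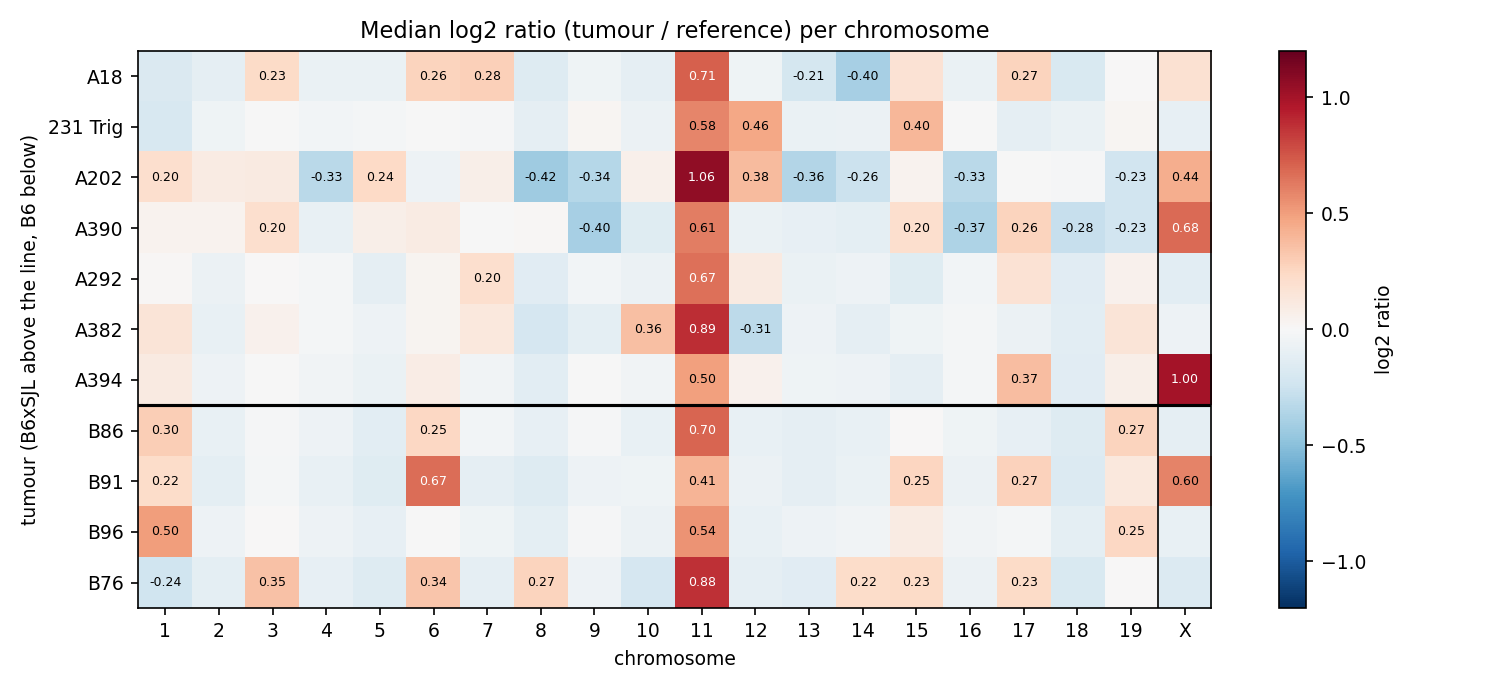
Median log2 ratio of tumour over reference for each chromosome, X included, in each of the 11 tumours, as a heat map with values of at least 0.2 in size printed. Chromosome 11 is the column where all 11 tumours are above the reference, from 0.41 to 1.06.

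The reference channel itself was lower on chromosome 11. After adjustment for the GC content of the probes, its median there was -0.52 ± 0.04 log2 (SD, n = 12 arrays) relative to the array, against -0.09 to 0.16 on the other autosomes. The tumour channel on chromosome 11 ran from -0.08 in B91 to 0.45 in A202, and reached 0.2 in 3 of 11 tumours: A202, A382 (0.36) and B76 (0.34). Ratios of all genes on chromosome 11 given below carry this shift of the reference channel.

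**Figure D2:**
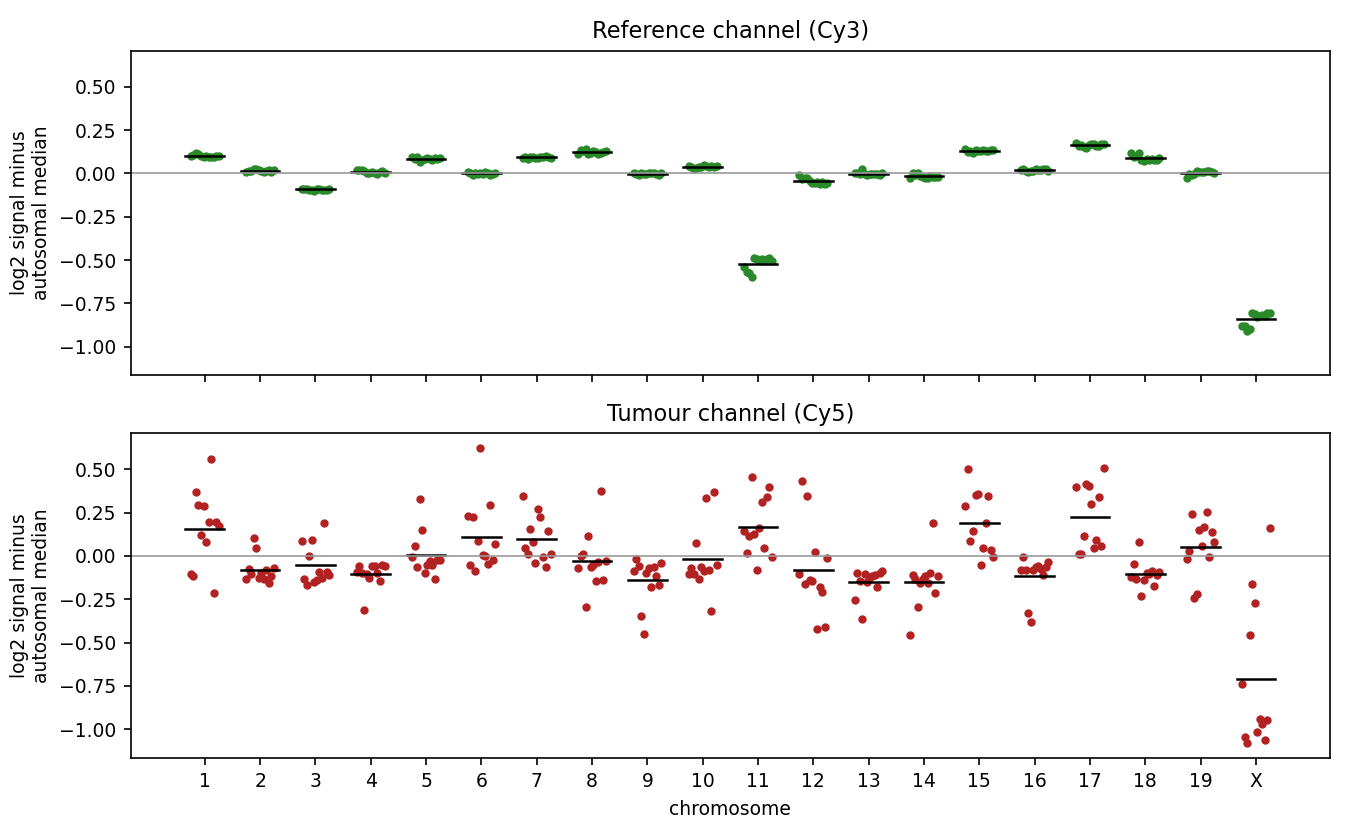
Median signal of each chromosome in the reference channel and in the tumour channel (log2, adjusted for GC content, relative to the array) on the 12 arrays, with the mean as a black line. The reference channel on chromosome 11 lies at -0.52 on average, below every other autosome, while the tumour channel there spreads from -0.08 to 0.45 across tumours.

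Single tumours carried their own chromosome-wide changes. In A202, chromosomes 8 (-0.42), 13 (-0.36), 9 (-0.34), 4 (-0.33) and 16 (-0.33) were lower and chromosome 12 (0.38) was higher. A390 was lower on chromosomes 9 (-0.40) and 16 (-0.37), and A18 was lower on chromosome 14 (-0.40). Higher medians included chromosomes 12 and 15 in 231 Trig (0.46 and 0.40), chromosome 1 in B96 and B86 (0.50 and 0.30), chromosomes 3 and 6 in B76 (0.35 and 0.34) and chromosome 17 in A394 (0.37). A382 was higher on chromosome 10 (0.36) and lower on chromosome 12 (-0.31). There is 1 array per tumour for these values, except A382, so they carry no test.

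At the level of genes, the lowest means included Cdkn2a, which encodes the cell cycle inhibitors p16INK4a and p19ARF, and the highest included a gene of the Skint family, which encodes immunoglobulin-like proteins of skin and thymus. Cdkn2a (chromosome 4, 88934358 to 88938124) fell by 2.30 ± 1.96 log2 (SD, n = 11, limma adjusted p 0.000748). Genes with high means were the cDNA AK155119 on chromosome 11 (2.79), AK036813 near Myc (1.21), the taste receptor gene Tas2r120 (1.19) and Skint4 (1.04). AK155119, Tas2r120, and Klra22 and Tom1l1 below, had probes that were not well above background on every array, and at 1 AK155119 probe the reference channel was -4.20. Other low means were Nxpe5 (-2.38), AY512931 (-1.79), AK046613 (-1.68) and the carboxypeptidase gene Cpb1 (-1.62), each from a single probe inside a segment with a mean between -0.11 and 0.07. With the running median of 5 probes the calls on Nxpe5 (-0.06), AY512931 (-0.16), AK046613 (-0.12) and Cpb1 (0.09) ended. That on AK036813 ended without slide 1 (1.42, limma adjusted p 0.0541) and in C57BL/6J tumours only (1.46, limma adjusted p 0.193), the range over its alternatives being 0.0104 to 0.193. Of 19970 genes, 3600 rose and 3084 fell. Chromosome 11 held 41.4% of those that rose, and 1492 of its 1556 genes rose. Outside it 2108 rose and 3082 fell, of which 73 and 11 lay in segments with a mean past 0.2 in size over the tumours, and 9.58% and 30.1% in segments called in no tumour.

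Focal losses centred on Cdkn2a. In 6 tumours the stretch containing it was far below the reference: 231 Trig (-3.51 over 1511 kb, which also took in Mllt3, the interferon gene Ifnb1 and Mtap), B86 (-3.07 over 1165 kb), B91 (-2.72 over 460 kb), B96 (-3.65 over 312 kb), A382 (-3.79 over 105 kb) and A394 (-3.26 over 9.67 kb). The loss in A394 covered 3 probes. A292 (-0.97) and A202 (-0.42) had smaller decreases at the gene, while A390 (-0.17), A18 (-0.06) and B76 (-0.09) stayed near 0.

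**Figure D3:**
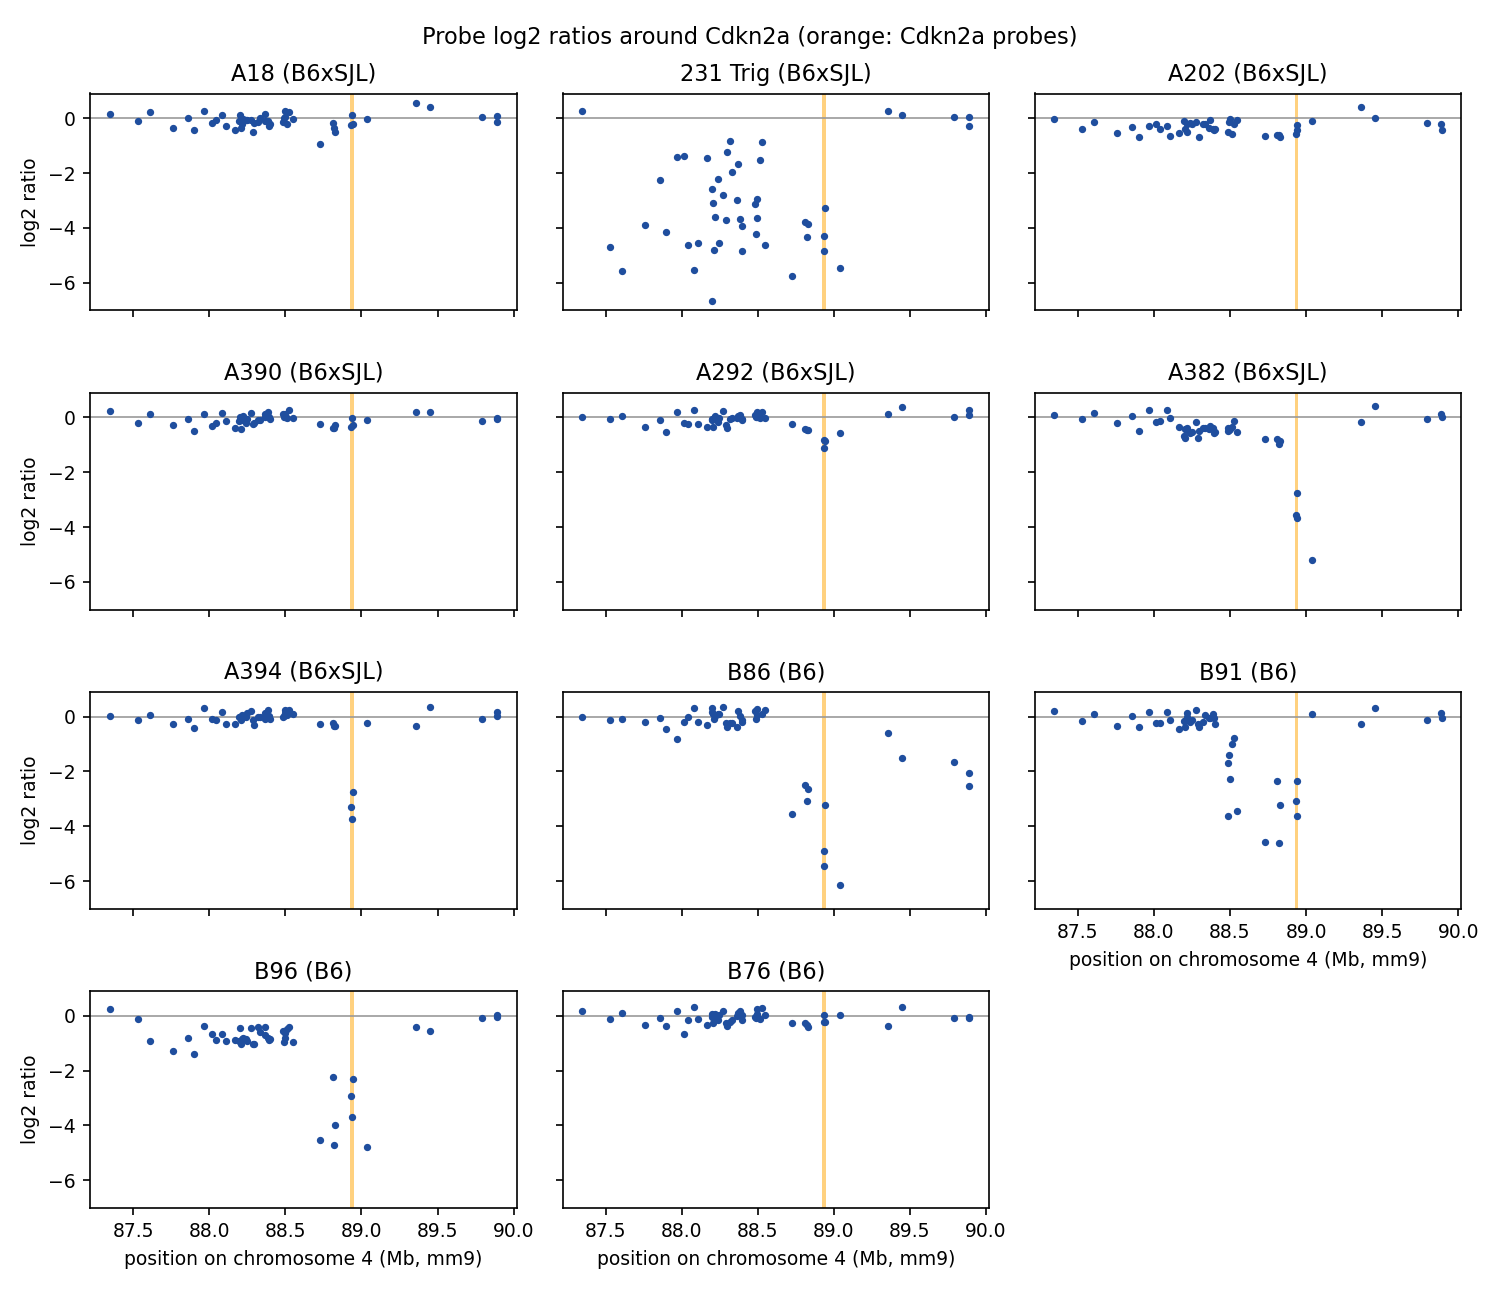
Log2 ratio of each probe along chromosome 4 around Cdkn2a, with position in Mb, in 1 panel per tumour and the Cdkn2a probes in orange. The probes drop to means between -2.72 and -3.79 in 6 tumours over stretches of 9.67 to 1511 kb.

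Myc, a transcription factor that drives growth, was at high ratios in 3 tumours: B76 (4.47), A390 (3.30) and A202 (2.40). The raised stretches around it measured 2049 kb, 3536 kb and 1503 kb, of which that in A390 joined 2 called segments, at 3.00 and 2.39. In A390 further stretches of chromosome 15 were raised as well, at 2.93 with Ghr and Oxct1 (3229082 to 4824354) and at 3.09 with Trappc9 and the cDNAs AK005816, AK043571 and AK010095 (71284306 to 72565804). In B76 the stretch with Sema5a and Sdc2 stood at 1.59. The mean for Myc just passed (0.97 ± 1.64, SD, n = 11, limma adjusted p 0.0493). The call ended without A18 (adjusted p 0.0571), 231 Trig (0.0502), A202 (mean 0.83, adjusted p 0.123), A390 (0.74, 0.126) or B76 (0.62, 0.0961), and in 13 of 24 alternatives (adjusted p 0.0413 to 0.309). A18 had raised segments on chromosome 10 (125404379 to 127428063, 1.22), which holds the hedgehog factor gene Gli1, Ddit3 and Kif5a, and on chromosome 7 (12807782 to 14904306, 1.21) with Trim28 and the DNA ligase gene Lig1. Its lowest segment, with the olfactory receptor genes Olfr1046 and Olfr1048, stood at -3.49, and A202 had the same stretch at -3.08. An overlapping segment in 231 Trig (85976436 to 86076093) stood at -0.91. Calls there came only from mixed tumours, all on slide 1, and whether they go with strain background was not tested. The stretches of A18 on chromosomes 7 and 10, of A390 at Ghr and of B76 at Sema5a were chosen after their values were seen. The highest segment in 9 tumours lay at AK155119, with St6galnac1, St6galnac2 or Mxra7, from 1.41 in B91 to 2.83 in A202. These segments had 5 probes, the fewest allowed, and which of the flanking genes they took in varied between tumours. AK155119 had 3 of the probes, at means of 2.31 to 3.47, not all well above background on every array. Whether the flanking genes themselves were raised was not tested. The lowest segment in A390 held Atf6 and Olfml2b (-0.83).

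The share of autosomal probes in called segments was 26.3% ± 12.2 (SD, n = 11), from 11.8% in A394 to 48.3% in A202. It depends on the call threshold, and at 0.1 the mean share was 53.2%. Gains made up 19.2% ± 7.37 and losses 7.01% ± 9.68 (SD, n = 11), with losses at 4.63% without A202 (30.7% in it), and without chromosome 11 the share was 20.5%.

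Calls piled up at a few places. Losses peaked at Cdkn2a on chromosome 4, with 8 of 11 tumours called. In A202 the call was part of a segment at -0.35 (62185428 to 98700003). The stretch around it with Mtap and Ifne (88494551 to 89039446) had loss calls in at least 5 tumours. The segments of B86, A292 and A394 started at 88727113, 88811955 and 88822721, past Ifne (88525953). Losses also met at Cd244a and Itln1 on chromosome 1 (173444942 to 173494003), with 6 tumours. Of these A18 was called there only as part of a segment at -0.21 (23373324 to 196997388) and had no focal drop, with probes at -0.03 to 0.14 from their neighbours. Gains covered chromosome 11 in 11 of 11 tumours. They also met at Skint3, Skint4 and Skint9 (chromosome 4, 111656718 to 112130148) in 10 tumours and at 1700047I17Rik1 (chromosome 12, 56227337 to 56247507) in 8, of which 231 Trig (0.47) and A202 (0.37) were called as part of segments along the whole chromosome. With chromosome 11 left out, a stretch of chromosome 17 with the formyl peptide receptor genes Fpr1, Fpr2 and Fpr3, Has1 and Lnpep (17572117 to 21647442) was counted as well, with 7. A18 (0.26) was again called by a segment along the whole chromosome. In A390, B91, A292, B76 and A394 the segments over it were 8.08 to 20.3 Mb long. Only B96 had a segment with these edges, at 0.22. The peaks of gain and of loss each had a family-wise permutation p of 0.000999, the smallest that 1000 shifts can give. In these shifts 8 tumours were needed for gain and 5 for loss, which 2991 and 19 probes reached. The shifts move each tumour's calls separately, but the reference was on every array, so its own changes would recur too. Its channel was at -0.52 on chromosome 11, -1.06 at Skint, 1.81 at Cd244a and -0.07 in the chromosome 12 stretch. On chromosome 11, at Skint and at Cd244a the test thus cannot tell recurrence in the tumours from a shift of the reference. In the chromosome 12 stretch (56206091 to 56247507) the C57BL/6J tumours averaged 0.84 ± 0.03 (SD, n = 4). A probe, dye or strain effect would repeat there too, and the test does not separate it from recurrent gains. Without B91 or B96 the probes with recurrent loss numbered 12. They numbered 2470 at a call threshold of 0.1, 36 at 0.3 and 43 with a penalty of 20.

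**Figure D4:**
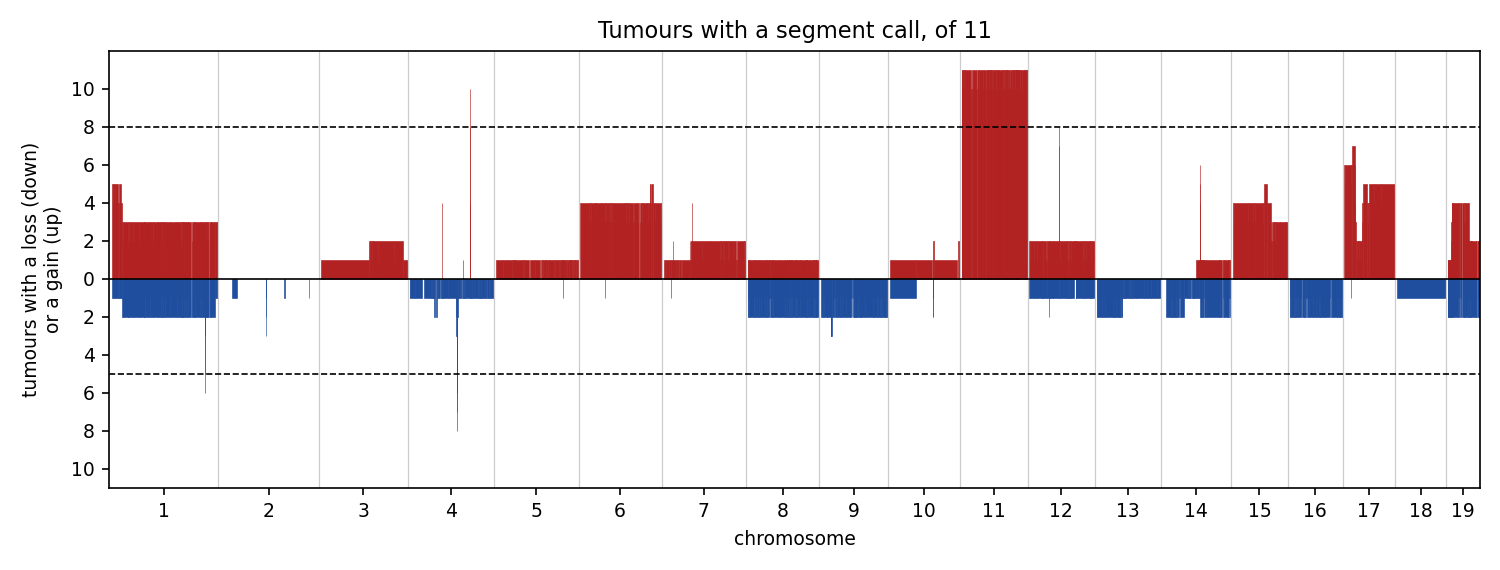
Number of tumours with a gain call (upwards) or a loss call (downwards) along the autosomes, with dashed lines at the counts needed in random shifts, 8 for gain and 5 for loss. Chromosome 11 reaches 11 tumours for gain, and the stretch with Cdkn2a reaches 8 for loss.

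Among 18 measured tumour suppressors of nerve sheath tumours, 4 rose, 4 fell and 10 did not pass, with the same 4 and 4 when adjusted over the list alone. All 4 that rose lie on chromosome 11: Trp53 (0.98 ± 0.29, SD, n = 11), the merlin gene Nf2 (0.79), the Polycomb gene Suz12 (0.64) and the neurofibromin gene Nf1 (0.64, with 4 probes from -0.14 to 1.28). Besides Cdkn2a, the genes Rassf1 (-0.31), Stk11 (-0.26) and the chromatin remodeller gene Smarcb1 (-0.22) fell. The segments around Rassf1, Stk11 and Smarcb1 averaged only -0.10, -0.07 and -0.06, and Rassf1 and Stk11 had 1 probe each. Rb1 (-0.09) and Eed (0.00), another Polycomb gene, did not pass. The list mean was -0.004 and the median 0.01, while fry gave the direction up (adjusted p 0.0114). The sign of the mean thus differed from that of the median and the test. Without chromosome 11 the list mean was -0.22 and the direction down (fry adjusted p 0.0140, range over the alternatives 0.00274 to 0.0349). That mean includes Cdkn2a at -2.30, far below the next lowest member, Rassf1 at -0.31, so it does not show a loss across the list.

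Of 21 receptor tyrosine kinases and ligands, 4 rose, 5 fell and 12 did not pass, with 4 and 5 adjusted over the list alone. Egfr (0.68) and Erbb2 (0.50), on chromosome 11, rose with Tgfa (0.41), an Egfr ligand, and Erbb3 (0.21), which encodes a neuregulin receptor. Hgf (-0.66), which encodes the ligand of Met, and Pdgfra (-0.60) fell in 11 of 11 tumours, although the segment around each averaged -0.05. The neuregulin gene Nrg1 fell by 0.26 ± 0.15 log2 (SD, n = 11). The list fell in fry (mean -0.02, median -0.06, adjusted p 0.00345). Its mean was -0.09 without chromosome 11 and turned to 0.006 with mode centring, with the direction down in both (adjusted p 4.88e-06 and 0.0262). Erbb3 was below the size minimum without B86 (0.19), A202 (0.20) or A382 (0.17), and at -0.05 with the running median of 5 probes, where Pdgfra (-0.09) also lost its call. The call on Erbb3 further ended with slide as a block (0.197), without slide 1 (0.19) and in C57BL/6J tumours only (0.18, limma adjusted p 0.0623). Nrg1 did not pass in C57BL/6J tumours only (-0.18). Met, at 0.20, lay just under the size minimum and passed in 13 of 24 alternatives. Among these were leaving out A18, 231 Trig, A202, A390, A382 or A394 (0.20 to 0.24), slide as a block (0.20), normexp (0.24), loess (0.22), mode centring (0.23) and the running median (0.25). Its mean was 0.03 in mixed and 0.49 in C57BL/6J tumours, a difference that did not pass (limma adjusted p 0.194). Met lies on chromosome 6, whose medians were 0.67 in B91, 0.34 in B76, 0.25 in B86 and -0.01 in B96. Met also passed in C57BL/6J tumours only (0.49, limma adjusted p 0.0127) and with equal weight for both backgrounds (0.26). Its limma adjusted p ranged from 0.000583 to 0.0802 over the alternatives.

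Ratios of genes of Ras, MAPK and PI3K signalling lay, on balance, below the reference. Of 25 measured, 1 rose, 6 fell and 18 did not pass, with the same counts adjusted over the list alone (mean -0.09, median -0.11, fry adjusted p 9.91e-06). Pik3r1, the regulatory subunit gene of PI3K (-0.47), Rras (-0.39) and Map2k2 (-0.27) fell. The segments around the 6 genes that fell averaged only -0.12 to 0.03, and among all genes 15.4% fell. Akt2 was the gene that rose (0.34), with probes at -0.10 and 0.77, and it was at -0.04 with the running median of 5 probes, where Rras (-0.02) also lost its call. Akt2 did not pass in C57BL/6J tumours only either (0.30, limma adjusted p 0.0816).

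Cell cycle, mitosis and Myc genes moved the other way, with 5 of 19 rising, none falling and 14 not passing (4 rose when adjusted over the list alone). Besides Myc, the spindle checkpoint gene Mad2l1 on chromosome 6 (0.75), Top2a (0.66) and Birc5 (0.55), both on chromosome 11, and the mitotic transcription factor gene Foxm1 (0.37) rose. Mad2l1 had 1 probe, in a segment with a mean of 0.14. The list mean was 0.17, the median 0.04 and the fry adjusted p 7.31e-05, with the direction up. That mean includes Myc at 0.97, which was at high ratios in 3 tumours. Without chromosome 11 the list mean was 0.12 (fry adjusted p 0.00907). In the DNA damage and telomere list, 2 of 12 rose, Brca1 on chromosome 11 (0.74) and the Ku gene Xrcc6 (0.27), and 1 fell, the telomerase gene Tert (-0.30). The other 9 did not pass, and the counts adjusted over the list alone were also 2 and 1. Its fry test gave up (mean 0.10, median 0.10, adjusted p 7.31e-05), but not without chromosome 11 (mean 0.04, adjusted p 0.138, range over the alternatives 2.31e-05 to 0.138). The running median of 5 probes ended the calls on Tert (-0.14) and Xrcc6 (0.16).

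In the Schwann cell lineage list, 3 of 12 measured genes rose, 2 fell and 7 did not pass, with 3 and 2 adjusted over the list alone. The neurotrophin receptor gene Ngfr (0.86) and the myelin gene Pmp22 (0.44), both on chromosome 11, and Mag (0.24) rose. Pou3f1, a transcription factor gene of promyelinating Schwann cells (-0.31), and Gap43 (-0.29) fell. With the running median of 5 probes Pou3f1 (-0.16) was below the size minimum. The list rose in fry (mean 0.12, median 0.10, adjusted p 7.31e-05), but not without chromosome 11 (mean 0.01, adjusted p 0.194, range over the alternatives 4.63e-05 to 0.194).

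At loci that differ in copy number between inbred strains, 5 of 11 genes rose, 2 fell and 4 did not pass, with 5 and 2 adjusted over the list alone. The natural killer cell receptor genes Klra22 (0.86), Klra17 (0.44) and Klra2 (0.36) rose in 11 of 11 tumours, and the dynein gene Dnah8 (-0.45) and its neighbour Glo1 (-0.33) fell. Klra2 lost its call with the running median of 5 probes (0.09). The list did not pass (mean 0.13, median 0.19, fry adjusted p 0.0632), but did without B91 (mean 0.09, adjusted p 0.0105, range over the alternatives 0.0105 to 0.255). None of the 12 lymphocyte antigen receptor loci was measured under its name, so 0 genes were tested with fry.

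The second comparison, between the 7 tumours on the mixed background and the 4 on C57BL/6J, asks whether strain background goes with copy number. Gapdhs, a sperm-specific glycolytic enzyme gene on chromosome 7 (31523443 to 31523502), was higher in the mixed tumours by 1.23 ± 0.14 log2 (SE, limma adjusted p 0.00305), with values of -0.34 to 0.32 against -1.49 to -0.82. Tom1l1, an endosomal trafficking gene on chromosome 11 (90535960 to 90544667), was higher by 1.21 ± 0.13 (SE, limma adjusted p 0.00169), although its 2 probes differed and 1 of them varied by an SD of 1.34 against 0.29. Lmo4, a LIM domain transcription regulator gene on chromosome 3 (143863148 to 143863207), was higher by 0.69 ± 0.10 (SE, limma adjusted p 0.0234). These 3 genes passed out of 19970, with 2050 at an unadjusted p under 0.05, and every mixed tumour lay above every C57BL/6J tumour at each. Within slides 1, 2 and 3 the difference was 1.41, 0.85 and 1.29 for Gapdhs, 1.47, 1.06 and 0.74 for Tom1l1, and 0.57, 0.93 and 0.58 for Lmo4. With slide as a block the limma adjusted p was 0.0410, 0.0160 and 0.111, and over the alternatives it ranged from 0.00128 to 0.518, from 9.66e-05 to 0.672 and from 0.0165 to 0.546. The count was 8 without 231 Trig, 10 without A390, 5 without A382 and 7 without A394, and Lmo4 did not pass without B86 (limma adjusted p 0.0591), A202 (0.0625), B91 (0.145), A292 (0.0514) or B96 (0.155), nor with mode centring (0.0658). With the running median of 5 probes 0 genes passed in limma (2019 at an unadjusted p under 0.05), and without slide 1 also 0 (1268), although the differences were then 1.17 for Gapdhs, 1.09 for Tom1l1 and 0.73 for Lmo4. Gapdhs and Lmo4 rest on 1 probe each, and with the running median the differences were 0.15 for Gapdhs, 0.11 for Tom1l1 and 0.13 for Lmo4. The varying probe of Tom1l1 stood apart from its neighbours by -2.69 on average in the C57BL/6J tumours.

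By chromosome, 0 of 19 autosomes passed between the backgrounds in the exact permutation test, with 1 at an unadjusted p under 0.05. This was chromosome 7, at a difference of 0.16 (mixed 0.09 ± 0.12, n = 7, and C57BL/6J -0.07 ± 0.04, n = 4, SD, exact p 0.0303, adjusted p 0.360). Its difference was 0.15, 0.22 and 0.03 within the 3 slides. Chromosome 6 was lower in the mixed tumours (-0.24, exact p 0.0515), by -0.13 without B91, and by -0.18, -0.61 and -0.07 within the slides. The share of probes gained was 15.9% ± 5.74 (SD, n = 7) in mixed and 25.1% ± 6.67 (SD, n = 4) in C57BL/6J tumours. That difference of -9.13 points had an exact permutation p of 0.0485 and 0.194 after adjustment over 4 measures, its unadjusted exact p was 0.00952 to 0.394 in 22 alternatives (under 0.05 in 7) and 0.0286 to 0.418 adjusted over 3 measures, passing only without A18 (-11.2 points), and it was -3.07, -14.6 and -13.0 within the slides. The share lost (7.27 points, exact p 0.282) and the total share altered (-1.86 points, exact p 0.803) did not differ by more than the spread. Leaving out each tumour gave 3.76 (without A202) to 9.13 (without B76) for the share lost and -5.64 (without A202) to 2.47 (without B76) for the share altered. Within the slides the differences were 14.2, 6.84 and -3.84 for the share lost and 11.1, -7.80 and -16.9 for the share altered, so both changed sign, and at a call threshold of 0.1 the share lost differed by -7.72.

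The arrays of A382 at passages 8 and 9 ask whether the profile changed in culture. The profiles correlated at r = 0.967 across probes, which are not independent replicates, and the Cdkn2a loss was in both. Segment means differed by at least 0.2 over 0.270% of probes, in 5 stretches. The longest was on chromosome 12 (83576561 to 86322139, 78 probes), where the probe mean was -0.20 at passage 8 and -0.03 at passage 9. Its genes with the largest difference were Dnal1 (-0.24 and 0.09), BC033459 (-0.18 and 0.11), Lin52 (-0.05 and 0.22), BC057351 (-0.31 and -0.04) and AK036130 (-0.06 and 0.21). In 3 of the 5 stretches, at Pcgf2, Srp54a and Glo1, the probe means were nearly equal and only the placement of segments differed. The share altered was 23.7% at passage 8 and 16.5% at passage 9, and the share lost 9.09% and 3.60%. Since segment means differed by at least 0.2 over only 0.270% of probes, most of this came from smaller differences across the call limit. In the mean of both arrays, a segment along chromosome 8 stood at -0.202, next to that limit. There was 1 array per passage, so no test was made. Passage 8 was on slide 2 and passage 9 on slide 3, so passage and slide cannot be told apart.

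Across the 10 tumours with a passage number, the share of altered probes did not go detectably with passage (Pearson r = 0.436, permutation p 0.209, Spearman rho = 0.394, permutation p 0.260). Chromosome 11 left out gave r = 0.436, and the adjusted p over both relations was 0.209. At a call threshold of 0.1 r was 0.656 (permutation p 0.0370, range over the alternatives 0.00822 to 0.806). Without the 2 tumours farthest from the median passage r was -0.0771. The absence of a detectable relation depends on A202, without which r was 0.808 (permutation p 0.00822). The other tumours left out in turn gave r from 0.262 (without B76) to 0.470. Within slides r was 0.614 (exact permutation p 0.25, 864 orders), at 0.189, 0.0571 and 0.977 on slides 1 to 3 with 3, 4 and 3 tumours.

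On X, the median ratio was 1.00 in A394, 0.68 in A390, 0.60 in B91, 0.44 in A202 and 0.18 in A18, and -0.16 to -0.06 in the other 6 tumours. The reference channel on X was -0.84 ± 0.04 log2 (SD, n = 12 arrays) relative to the array, and the tumour channel ran from -1.08 in B86 to 0.16 in A394. The sex of the tumours and of the reference is not given in the sources used here, so copy changes on X cannot be told apart from a difference in sex.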

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

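The tests of the reference copies, of GC content and brightness and of the tumours as the whole cause on chromosome 11 and of a probe or dye effect at isolated probes, for the set and for those raised in every tumour, were chosen only after the result was seen, as were the comparisons within slides. The other tests below were set down before their result was seen.

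Chromosome 11 was above the reference in every tumour. On 12 of 12 arrays the reference channel, adjusted for GC content, was lower on chromosome 11 than on every other autosome, by -0.43 log2 on average against the lowest of them, which argues against extra copies in the tumours as the whole cause. GC content and brightness are argued against as well, since the mean after adjusting for both was 0.69 (0.69 before), and a focal part is too, since 10 of 10 equal parts of chromosome 11 lay below the lowest 5% of parts elsewhere. Fewer copies of chromosome 11 in the reference DNA remain a candidate explanation for the shared shift, which would bear on the ratios of Trp53, Nf1, Nf2, Suz12, Egfr and Erbb2 alike. Gains in single tumours such as A202 (tumour channel 0.45) stay open.

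At 57 isolated probes all 4 C57BL/6J tumours lay over 1 log2 above the median of their neighbours (a window of 21 probes), and at 40 over 1 below, and only 1 of 330 sets of 4 tumours, the real one, had as many raised probes (the highest other 44), which argues against chance over sets. A probe or dye effect common to all arrays is argued against for the raised probes as a set, since 31.8% of the mixed tumours' values there were within 0.5 of their neighbours, but 46.1% were raised by over 1, and the effect stays open at the 9 probes raised in every tumour. The reference channel was low at the raised probes by 106% of the median excess in the ratio (bootstrap 77.3% to 132%), so sequence that is missing or changed in the reference DNA may account for them. At the lowered probes the reference channel was 0.35, the C57BL/6J tumour channel -1.18 and the median excess -1.65, so the reference does not account for most of it there. Whether the reference shares its strain with these tumours, as its label gives, and strain background itself stay open.

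A test of samples that lie far from the rest of their strain group marked 19 of 132 groups, where chance marks about 1 in 20, or 6.6. The groups are not independent, since Myc and AK036813 share the raised stretch of B76, and some genes were named for extreme means. The excess of 19 over 6.6 is therefore no test of chance. B76 stood apart from the other C57BL/6J tumours on chromosome 3 (0.35, others -0.02 to 0.01) and chromosome 8 (0.27, others -0.15 to -0.10). Its share of probes lost was 7.96% (others 0.0446% to 1.39%). Its value was 4.57 at AK036813 (others 0.12 to 0.74), 4.47 at Myc (-0.17 to 0.23), 0.95 at Egfr (0.58 to 0.64) and 0.97 at Skint4 (1.21 to 1.25). B91 stood apart on X (0.60, others -0.16 to -0.08, with the sex of each not given), and B86 at Akt2 (-0.11, others 0.42 to 0.47) and Erbb3 (0.36, others 0.11 to 0.15).

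Among the mixed tumours A202 stood apart on chromosome 4 (-0.33, others -0.09 to -0.03) and at 4 genes: Tert (-0.59, others -0.31 to -0.14), Nrg1 (-0.56, others -0.31 to -0.20), Pdgfra (-0.10, others -0.70 to -0.49) and Tas2r120 (0.027, others 1.10 to 1.49). A382 did on chromosome 10 (0.36, others -0.14 to 0.06) and at Erbb3 (0.58, others 0.09 to 0.28). A18 did in its share gained (28.1%, others 11.6% to 17.5%) and at Skint4 (-0.022, others 0.80 to 1.30).

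A difference between the strain backgrounds, tested in limma, marked Gapdhs (1.23), Tom1l1 (1.21) and Lmo4 (0.69). Chance cannot be excluded for this count of 3 genes, since 5 of 100 splits of the tumours into 7 and 4, the real one included, had as many (4 of the other 99), which is a share of 0.05, at the limit. The highest count of the other splits, 119, came from the split that sets the 4 tumours of slide 1 (A18, 231 Trig, B86 and A202) against the rest, so these samples carry a structure other than strain. Within slides 1, 2 and 3 the differences were 1.41, 0.85 and 1.29 for Gapdhs, 1.47, 1.06 and 0.74 for Tom1l1, and 0.57, 0.93 and 0.58 for Lmo4, and with slide as a block the limma adjusted p was 0.0410, 0.0160 and 0.111.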

How the results depend on the processing

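Leaving out slide 1, leaving out chromosome 11, segmentation without limiting isolated probes, slide as a block for the lists, the comparisons within slides and leaving out each tumour for the shares and the passage correlation were chosen only after seeing the data. Of the values that answer a comparison, 422 stayed on their side under the alternatives, 30 moved, 2 became weaker, 4 stronger and 1 reversed. Of values for single genes and chromosomes, 1540 stayed, 61 became weaker, 22 stronger, 8 moved and 5 reversed. Of 38 named genes that passed, 22 did so in every alternative that gave them a value. The series value table gave identical values and changed nothing. Centring on the mode moved the counts to 4158 gained and 2369 lost, with the median of the gene means at 0.02 in place of -0.01. Signal limits little, since at least 99.4% of probes were well above background on each array. Where no reason is given below, the cause was not tested.

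Genes that rose or fell numbered 4273 with the running median of 5 probes, 10526 with no size minimum and 3578 with a minimum of 0.3, and the last 2 differ by construction. Those that fell numbered 5183 by single probes, 1590 with the running median, 5459 with no minimum and 1280 at 0.3. Those that rose numbered 2298 at 0.3 and 2104 without chromosome 11, which removes its genes. Leaving out each tumour gave 6500 to 6838 in total, 3442 to 3692 that rose and 3018 to 3179 that fell. Strain genes, 3 in the main setting, numbered 16 with normexp, 16 with loess, 5 with probes well above background, 12 by single probes, 0 in limma with the running median (2019 unadjusted), 0 in limma without slide 1 (1268 unadjusted, with fewer samples) and 2 to 10 leaving out each tumour.

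With the running median Cpb1 turned to 0.085, Akt2 to -0.038, Erbb3 to -0.052 and the mean of Gapdhs to 0.16. Tom1l1 turned to -0.71 in C57BL/6J tumours only. The tumour suppressor list, which holds Cdkn2a at -2.30, turned to -0.22 without chromosome 11, where its risers lie. Its mean ranged from -0.028 to 0.022 leaving out each tumour. Without chromosome 11 the DNA damage list weakened to 0.040 and the Schwann cell list to 0.012. The list of strain loci ranged from 0.088 to 0.15 leaving out each tumour, and 6 to 7 lists passed (main 6). Autosomes passing numbered 6 to 9 leaving out each tumour (main 7).

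Leaving out each tumour gave a strain difference in the share gained of -11.9 to -6.66 points (-11.2, past the threshold, without A18), in the share lost of 3.76 to 9.13 and in the share altered of -5.64 to 2.47, a share altered of 24.1% to 27.7% and a passage correlation of 0.262 to 0.808 (the last, past the threshold, without A202). At a call threshold of 0.1 the share altered was 53.2%, the strain difference in the share lost -7.72 points, the passage correlation r = 0.656 and the probes with recurrent loss 2470. The last numbered 36 at 0.3, 43 with a penalty of 20, 11 without slide 1 and 12 to 19 leaving out each tumour. Probes with recurrent gain numbered 71 without chromosome 11, and 2983 to 2989 leaving out each tumour. Without slide 1, with fewer tumours, the highest loss count was 5 and the loss calls at Cdkn2a 5, against 7 to 8 for each leaving out 1 tumour.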

Other observations

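The stretches below were chosen after their values were seen. Besides Skint3, Skint4 and Skint9 on chromosome 4 (111745389 to 112130148), which averaged 0.79 in the C57BL/6J tumours, 3 short stretches were called in all 4 of these tumours. Srp54a, a signal recognition particle gene, lay in one on chromosome 12 (56206091 to 56247507, 0.84). Entpd4 and the mitochondrial iron importer gene Slc25a37 lay in another on chromosome 14 (69877295 to 69987015, 0.90). Cd244a, an immune receptor gene, and Itln1 lay in one on chromosome 1 (173444942 to 173494003, -1.22). Of the mixed tumours 6, 4, 2 and 2 had calls there, in the order Skint, Srp54a, Entpd4 and Cd244a. At Srp54a the calls of 231 Trig and A202, and at Cd244a that of A18, came from segments along most of the chromosome. Among the mixed tumours the highest probe mean at Srp54a was 1.35, above the segments of A390 (0.86) and A382 (0.46). A focal rise in a tumour without such a short segment is thus not excluded. A18 had no focal drop at Cd244a, while 231 Trig had no call but lay -1.47 and -1.61 from the neighbours at 2 probes. The reference channel was -1.06, -0.07, -0.65 and 1.81 log2 in these stretches.

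At AK155119, 1 probe had a ratio over 2 in every tumour (mean 3.47), where the reference channel was -4.20 and the tumour channel -0.76. Alad, an enzyme gene of haem synthesis, with Hdhd3 and Bspry on chromosome 4 (62144188 to 62182553), stood at 1.25 in 231 Trig, 1.21 in A390, 1.01 in A202 and 0.81 in A18. This stretch was called only in these mixed tumours, and whether it goes with strain background was not tested. In B76 the stretch with Lig4, a DNA ligase gene of end joining, and Tnfsf13b on chromosome 8 (9475463 to 10516317) stood at 1.05.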
